A study of Mus musculus with 26 samples.

How the data were processed

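RNA sequencing of brown adipose tissue was analysed from 26 libraries of mice of the genotypes FF (both Klf15 alleles floxed, no Cre) and BKO (the same alleles with Cre under the Ucp1 promoter), 13 libraries each. Each genotype was sampled in 4 conditions, namely fed at room temperature, fasted at room temperature, in a cold challenge, and in cold plus fasting, with 4 libraries per genotype in cold and 3 in each other group. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), computed by the authors with STAR, Cufflinks and Cuffdiff on the mouse build mm10 per the submitters' processing notes, which give no versions for these programs. Read counts were not used here, so the depth of each library is unknown and no counting error can be given. The sum of FPKM per library ranged from 388107 to 501068, and 11345 to 11868 genes per library reached 1 FPKM. Gene IDs without their version were matched to GENCODE M21 on GRCm38, which held 48051 of them; 110 symbols stood on more than 1 ID, so genes were followed by ID.

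Zeros in abundant genes were treated as failed estimates. In 33 genes some libraries held exactly 0 while the smallest of the other values was at least 100 FPKM, and their zeros were removed; 30 of these genes were left out, and 3 were kept for the groups with values. Ucp1 was listed at 0 in 8 libraries, which are all those of the cold challenge, Gpd1 in 14, Fasn in 20 and Scd1 in 26, and 11 of the 13 mitochondrial protein genes were at 0 in all libraries. No difference was computed for these genes where a group had no value. Another 22533 genes were at 0 throughout the table.

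Genes with at least 1 FPKM in at least 3 libraries were tested, which left 12705. Values were analysed as log2(FPKM + 1), a scale that understates the fold of genes at low levels. A linear model with the 8 group means was fitted over all 26 libraries with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend, and contrasts of group means were tested with Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. The contrasts were BKO against FF in each condition and as the average of the 4 conditions, each condition against feeding at room temperature within each genotype, and the difference of each of those responses between genotypes. P-values of single genes measure the spread between libraries within groups, pooled over all 8 groups, of which each holds 3 or 4 libraries. Those of the gene lists described below compare list members with all other genes. Both kinds are two-sided. Another 4 contrasts were added after the results of the planned ones had been seen, namely cold plus fasting against cold within each genotype, and the difference between the fasting responses in the cold and at room temperature.

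Genes named in the text were taken by a rule set before the data were examined. It comprised 14 genes fixed by name, the 8 largest rises and 8 largest falls per comparison of genotypes or response of FF mice, the 5 largest each way in responses of BKO mice and in differences of responses, and up to 4 members with the smallest adjusted p of each list described. The ranked genes also had to reach 2 FPKM in the higher group. No overlap between the libraries compared was asked for as well, except in differences of responses, and for the average the same sign in all 4 conditions took its place. Some genes that the rule gave but whose calls ended without many of the libraries in turn were left out of the text. Some further genes that the rule gave are withheld items and are not reported here. Gene lists for pathways and for markers of other cell types were also set beforehand, 38 lists with 592 genes, of which 493 were tested and 2 were not in the table. The 33 lists with at least 5 tested genes were compared with all other genes by camera in limma with an inter-gene correlation of 0.01, and again with a correlation estimated from the data. Counts of list members that rose or fell were taken from adjustment over all genes and from adjustment over the list alone. Coordinates are those of GRCm38.

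The analysis was tested on simulated data with the same layout and 12702 genes. Of 100 genes given a log2 change of 0.5 between genotypes fed at room temperature, 61 were recovered, and of 100 with a change of 1, 92 were recovered, with 10 false calls. In cold the numbers were 71 and 98 with 7 false calls, and for the difference of fasting responses 16 and 78 with 3 false calls. In the list test the 1 list that had been shifted passed and 0 of the others did. The simulated noise was independent between genes and libraries, with no effect of library series or order, and changes were planted only in more highly expressed genes. These numbers therefore do not measure the error rates in the real data.

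Alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, array weights, a fit on only the libraries compared, the library number series as a covariate, only libraries numbered 15 or above, leaving out each library in turn, and the estimated correlation in the list test. The submitters' library numbers fall into a first series, 1 to 8, which holds FF mice only, and a second, 15 to 32, which holds both genotypes. All 3 FF libraries of fasted mice at room temperature were of the first series, as were 3 of the 4 FF libraries in cold and 2 of the 3 FF libraries fed at room temperature. Libraries were not paired, since the labels pair none and replicate numbers only follow the order of submission; resemblance between libraries of the same number was examined but not modelled. No library was left out of the results reported. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.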

Results

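The data comprised FPKM values of 26 libraries of mouse brown adipose tissue, the heat-producing fat depot. FF mice carried floxed Klf15 alleles without Cre, and BKO mice carried the same alleles with Cre driven by the Ucp1 promoter, which is active in brown adipocytes. Both genotypes were studied fed at room temperature (n = 3 libraries per genotype), fasted at room temperature (n = 3), in a cold challenge (n = 4) and in cold plus fasting (n = 3). The depth of the libraries is unknown, as read counts were not used here. Sequences of the Y-linked gene Ddx3y were present in every library, at 12.3 to 36.9 FPKM, while Xist lay between 0 and 0.0158 FPKM. Correlation between libraries had a median of 0.985 within groups and 0.968 between groups. The first principal component held 44.3% of the variance and parted fasted mice at room temperature from the others. BKO cold plus fasting replicate 3 stood apart on the third component, which held 5.8%, at a score of 27.12. Replicate 3 also had the highest score on it in every other group, such as 19.19 in fasted BKO mice, except fed FF mice (0.18, against 0.95 for replicate 2).

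**Figure D1:**
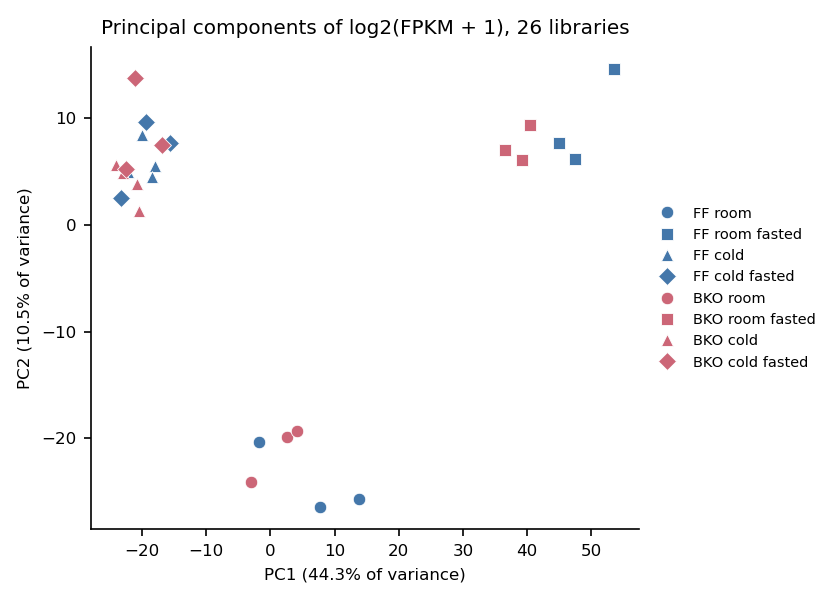
The first (x axis, 44.3% of variance) and second (y axis) principal components of log2(FPKM + 1) are plotted for the 26 libraries, colored by genotype, with a symbol per condition. Mice in cold and in cold plus fasting lie together, away from fed and from fasted mice at room temperature.

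Klf15, the targeted gene, a zinc finger transcription factor (ENSMUSG00000030087.11, chromosome 6, 90462576 to 90475238), was lower in BKO mice in all 4 conditions. Fed at room temperature it stood at 3.99 ± 1.03 FPKM in BKO and 28 ± 3.87 FPKM in FF mice (SD, n = 3 each), which is 14.3% of the FF level. In fasted mice at room temperature the levels were 8.56 ± 0.539 and 24.1 ± 5.18 FPKM (SD, n = 3 each), or 35.5%. In cold they were 2.42 ± 0.334 and 14.1 ± 3.45 FPKM (SD, n = 4 each), or 17.2%. In cold plus fasting 3.34 ± 0.483 and 17.8 ± 3.35 FPKM (SD, n = 3 each), or 18.7%. Every BKO library, at 2.12 to 8.92 FPKM, lay below every FF library, at 9.03 to 30.6 FPKM. The log2 difference was -2.55 (SE 0.19, adjusted p = 1.16e-08) fed, -1.38 (SE 0.19, adjusted p = 6.51e-05) fasted, -2.11 (SE 0.16, adjusted p = 2.25e-08) in cold and -2.11 (SE 0.19, adjusted p = 4.6e-07) in cold plus fasting.

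**Figure D2:**
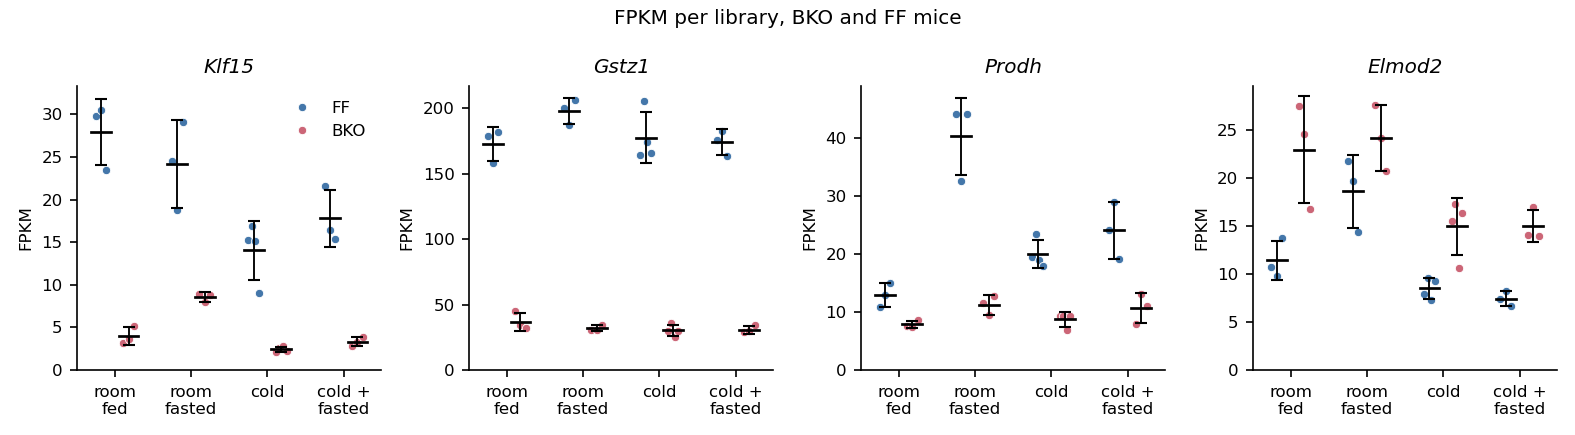
FPKM (y axis) of Klf15, Gstz1, Prodh and Elmod2 is plotted for each library by condition (x axis), with FF in blue and BKO in red and black lines for the mean and SD of each group. Klf15 lay at 2.12 to 8.92 FPKM in BKO and 9.03 to 30.6 FPKM in FF libraries, and Gstz1 was at 16.2% to 21.4% of the FF mean in BKO mice.

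Averaged over the 4 conditions, BKO mice had lower transcript levels of several enzymes that break down amino acids. Gstz1, maleylacetoacetate isomerase of tyrosine breakdown (ENSMUSG00000021033.10, chromosome 12, 87147165 to 87164723), showed the largest fall by the naming rule, at a log2 difference of -2.44 (SE 0.06, adjusted p = 2.38e-18). Adhfe1, a mitochondrial hydroxyacid transhydrogenase (ENSMUSG00000025911.14, chromosome 1, 9547948 to 9580673), fell by 1.75 (SE 0.06, adjusted p = 3.2e-16). Gstm7, a glutathione transferase, fell by 1.61 (SE 0.07, adjusted p = 4.55e-14). Hpd, the dioxygenase that acts in tyrosine breakdown, fell by 1.27 (SE 0.07, adjusted p = 3.8e-12). Prodh, proline dehydrogenase (ENSMUSG00000003526.11, chromosome 16, 18060357 to 18090203), fell by 1.15 (SE 0.08, adjusted p = 2.27e-09). Osbp2 and the peroxisomal membrane gene Pxmp2 fell by 1.12 and 1.04. Among the rises, Fndc5, the precursor of irisin, was higher by 0.77 (SE 0.09, adjusted p = 9.29e-06). Elmod2 was higher by 0.74 (SE 0.09, adjusted p = 8.14e-06), the glutathione transferase Gsta3 by 0.68, Fam131c by 0.57 and Tbc1d9 by 0.48. Elmod2 and Tbc1d9 are the tested genes on either side of Ucp1 on chromosome 8.

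Of 14 tested genes in the list for breakdown of amino acids other than the branched-chain ones, 0 rose, 8 fell and 6 did not pass (adjusted over the list alone, 0 rose and 10 fell; adjusted p = 0.00014 with an estimated correlation). Examples besides Hpd and Prodh were glutamate dehydrogenase Glud1 (-0.46) and the proline pathway gene Aldh4a1 (-0.58). Of 21 genes of branched-chain amino acid catabolism, 1 rose and 10 fell (adjusted over the list alone, 1 and 15; adjusted p = 0.0307 with an estimated correlation), among them Aldh6a1 (-0.84), Bcat2 (-0.72), Ivd (-0.64) and Mut (-0.57, SE 0.06). In the fatty acid oxidation list 5 of 28 genes rose and 2 fell (adjusted over the list alone, 13 and 2; adjusted p = 0.643 with an estimated correlation), with the mitochondrial genes Cpt2 (0.26) and Etfdh (0.19) higher. In the lipolysis and lipid droplet list 1 of 15 rose, Bscl2 (0.27), and 0 fell (adjusted over the list alone, 4 and 1; adjusted p = 0.318 with an estimated correlation). None of the 44 nuclear genes of oxidative phosphorylation passed by limma, with 0 also when adjusted over the list alone (adjusted p = 0.911 with an estimated correlation). Of the 14 genes fixed by name, 12 had values, of which 2 rose, 4 fell and 6 did not pass. Klf15, Prodh and Bcat2 kept their calls with each library left out, while that of Cpt1b ended without any 1 of 18 of the 26 libraries (adjusted p up to 0.1), that of Slc2a4 without any 1 of 15 (up to 0.0703) and that of Slc25a20 without FF cold plus fasting replicate 2 or BKO fasted replicate 3 (adjusted p = 0.0525 and 0.0546). In total 377 genes differed, 160 higher and 217 lower in BKO mice. Within single conditions, 575 genes were higher in fasted mice at room temperature, against 5 fed, 3 in cold and 2 in cold plus fasting. The higher calls of the average may therefore rest largely on fasted mice at room temperature, where series and genotype cannot be separated. With the library series as a covariate 59 genes passed, 5 higher and 54 lower, and with array weights 1344 did, 708 higher and 636 lower. The covariate ended the calls of Tbc1d9, Fam131c, Gsta3, Cpt2, Etfdh and Bscl2. The count was 242 without FF cold plus fasting replicate 2, 240 without FF fed replicate 1, 571 without FF fed replicate 3, 624 without FF fasted replicate 2 and 235 without BKO fasted replicate 3.

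Fed mice at room temperature gave the genotype difference without a challenge. Gstz1 was at 37.0 ± 6.92 FPKM in BKO and 173 ± 12.8 FPKM in FF mice (SD, n = 3 each; log2 difference -2.21, SE 0.12, adjusted p = 6.28e-11). Adhfe1 fell by 1.58 (SE 0.11, adjusted p = 7.31e-09), Gstm7 fell by 1.28 (SE 0.14, adjusted p = 6.82e-06) and the annexin Anxa8 fell by 1.24 (SE 0.12, adjusted p = 2.14e-06). Mycl fell by 1.28 (SE 0.21, adjusted p = 0.00387). Fndc5 was higher, at 6.02 ± 2.91 against 1.87 ± 0.13 FPKM (log2 difference 1.19, SE 0.19, adjusted p = 0.00387). Elmod2 was also higher, at 22.9 ± 5.55 against 11.4 ± 2.04 FPKM (log2 difference 0.93, SE 0.18, adjusted p = 0.026). Of the 14 other amino acid catabolism genes, 0 rose and 3 fell (adjusted over the list alone, 1 and 7; adjusted p = 0.02 with an estimated correlation), among them Hpd (-0.69). Of 21 branched-chain genes 0 rose and 2 fell (adjusted over the list alone, 0 and 4; adjusted p = 0.268 with an estimated correlation), among them Ivd (-0.50). None of the erythroid (5 tested), white adipocyte (9) or immediate-early (13) list members passed by limma, with medians of 0.78, 0.30 and 0.61 in BKO minus FF (adjusted over the list alone, 3, 1 and 0 rose; adjusted p = 0.359, 0.172 and 0.73 with an estimated correlation). In total 28 genes passed, 5 higher and 23 lower, and 742 had an unadjusted p under 0.05; with quantile normalization the split was 11 higher and 27 lower, and with array weights 424 higher and 362 lower. With the library series as a covariate 7 passed and in the second series alone, where FF mice have 1 fed library, 9 did, all of them lower, so that no higher call was left (Fndc5 1.20, adjusted p = 0.0791, and Elmod2 0.85, adjusted p = 0.51, with the covariate); those of Mycl, Hpd and Ivd also ended. The count was 15 without FF replicate 1, 14 without FF replicate 2, 105 without FF replicate 3, 15 without BKO replicate 2 and 13 without BKO replicate 3. The calls ended without BKO replicate 2 for Fndc5 (adjusted p = 0.0519), without BKO replicate 3 for Mycl and Ivd (adjusted p = 0.0519 for both), without FF replicate 1 or 2 or BKO replicate 1 or 2 for Elmod2 (adjusted p = 0.176, 0.228, 0.151 and 0.173), and without FF replicate 2 or 3 or BKO replicate 1, 2 or 3 for Hpd (adjusted p = 0.119, 0.0584, 0.0562, 0.0842 and 0.132).

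In fasted mice at room temperature, Selenbp1, Prodh and Gstz1 were lower and Adrb3 and Lgr6 higher in BKO than in FF mice, in libraries that also differed in series. Selenbp1, a methanethiol oxidase (ENSMUSG00000068874.13, chromosome 3, 94933056 to 94944758), was at 25.8 ± 3.91 FPKM in BKO and 114 ± 21.7 FPKM in FF mice (SD, n = 3 each; log2 difference -2.10, SE 0.15, adjusted p = 4.72e-09). Prodh was at 11.3 ± 1.72 against 40.3 ± 6.66 FPKM (log2 difference -1.75, SE 0.17, adjusted p = 7.92e-07), and Gstz1 fell by 2.59 (SE 0.12, adjusted p = 4.26e-12). The kinase Plk3, Adhfe1, Gstm7 and Pxmp2 fell by 2.02, 1.95, 1.81 and 1.78, and the ribosomal RNA gene n-R5-8s1 fell by 3.29 (SE 0.73, adjusted p = 0.00627). Adrb3, the main beta adrenergic receptor of adipocytes, was higher at 127 ± 43.5 against 47.0 ± 17.4 FPKM (log2 difference 1.41, SE 0.30, adjusted p = 0.00489). The R-spondin receptor Lgr6 was higher by 1.62 (SE 0.30, adjusted p = 0.00152), Fam131c by 1.34, the matrix protein Prelp by 1.26, Mfsd4b1 by 1.26 and the insulin receptor substrate Irs3 by 1.22.

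Of 28 fatty acid oxidation genes 13 rose and 1 fell in this comparison (adjusted over the list alone, 19 and 1; adjusted p = 0.118 with an estimated correlation), among them the carnitine pathway genes Cpt2 (0.79), Cpt1b (0.61) and Slc25a20 (0.49) and the dehydrogenase Acad11 (0.59). In the lipolysis and lipid droplet list 5 of 15 rose and 0 fell (adjusted over the list alone, 7 and 0; adjusted p = 0.118 with an estimated correlation), among them Plin1 (1.15, SE 0.17), Cideb (1.03) and Bscl2 (0.72). Other amino acid catabolism showed 0 rises and 7 falls among 14 genes (adjusted over the list alone, 0 and 8; adjusted p = 0.00393 with an estimated correlation), among them Hpd (-1.54), Aldh4a1 (-0.89) and Glud1 (-0.83). Branched-chain amino acid catabolism showed 1 rise and 9 falls among 21 (adjusted over the list alone, 1 and 12; adjusted p = 0.287 with an estimated correlation), with Aldh6a1 (-0.94, SE 0.13), Bcat2 (-0.91) and Ivd (-0.86) lower and Bckdk, the kinase that inhibits the pathway, higher (0.54). De novo lipogenesis showed 1 rise and 2 falls among 17 (adjusted over the list alone, 1 and 7; adjusted p = 0.695 with an estimated correlation), with Acly, ATP citrate lyase, lower by -1.57. In the PPAR and fasting-induced list 4 of 17 rose and 0 fell (adjusted over the list alone, 5 and 1; adjusted p = 0.643 with an estimated correlation), among them Acot2 (0.94) and Cyp4a10 (0.78). In the glucocorticoid-responsive list 0 rose and 4 of 17 fell (adjusted over the list alone, 1 and 6; adjusted p = 0.695 with an estimated correlation). The glucose transporter Slc2a4 was lower by -0.70 (SE 0.11, adjusted p = 0.000398), while Dio2 (-1.09, adjusted p = 0.0939) and Ucp1 (0.36, adjusted p = 0.31) did not pass. The coactivator Ppargc1a was called lower, but that call ended without FF replicate 1, 2 or 3 or BKO replicate 1 or 3 (adjusted p = 0.1, 0.0522, 0.0853, 0.157 and 0.0632). Skeletal muscle markers had a median difference of 1.25 over 11 genes, of which 1 passed, Myl1 (0.61; adjusted over the list alone, also 1; adjusted p = 0.839 with an estimated correlation). The Myl1 call ended without FF replicate 2 or 3 or BKO replicate 1, 2 or 3 (adjusted p = 0.112, 0.14, 0.119, 0.058 and 0.0998).

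In total 1102 genes differed between genotypes in fasted mice at room temperature, 575 higher and 527 lower in BKO mice, and Gstz1, Selenbp1 and Prodh were among those lower. All 3 FF libraries were of the first series and all BKO libraries of the second, so that series and genotype cannot be separated within this condition; with the series as a covariate, estimated from the other FF groups, 146 genes passed, 51 higher and 95 lower, and in a fit of only these libraries 76 did, 21 higher and 55 lower. The covariate ended the calls of Adrb3, Lgr6, Fam131c, Irs3, Cpt1b, Acot2, n-R5-8s1 and Myl1. The count was 447 without FF replicate 3 and 421 without BKO replicate 3.

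In the cold challenge transcripts of several enzymes of amino acid breakdown, such as Gstz1, Hpd and Bcat2, were again lower in BKO mice. Gstz1 was at 30.2 ± 4.52 FPKM in BKO and 178 ± 19.4 FPKM in FF mice (SD, n = 4 each; log2 difference -2.52, SE 0.11, adjusted p = 3.58e-13). Adhfe1 fell by 1.72 (SE 0.10, adjusted p = 1.04e-10). Gstm7 fell by 1.67 (SE 0.12, adjusted p = 5.33e-09), the paraoxonase Pon1 fell by 1.28 (SE 0.18, adjusted p = 0.000249). Prodh fell by 1.11 (SE 0.15, adjusted p = 0.000146), and Pecr, a peroxisomal reductase, and Ttc7 each fell by 1.05. Of the 14 other amino acid catabolism genes 0 rose and 6 fell (adjusted over the list alone, 0 and 9; adjusted p = 2.85e-05 with an estimated correlation), among them Hpd (-1.39), Aldh4a1 (-0.51) and Gcdh (-0.45). Of 21 branched-chain genes 0 rose and 5 fell (adjusted over the list alone, 0 and 11; adjusted p = 0.00274 with an estimated correlation), among them Aldh6a1 (-0.90), Bcat2 (-0.81), Ivd (-0.61) and Mccc2 (-0.37). In fatty acid oxidation 0 rose and 1 of 28 fell (adjusted over the list alone, also 0 and 1; adjusted p = 0.738 with an estimated correlation). In the ketone body (6 tested) and adipocyte differentiation (16) lists no gene passed over all genes by limma and 1 fell in each when adjusted over the list alone (adjusted p = 0.037 and 0.0154 with an estimated correlation). Only 3 genes were higher, among them Elmod2 (0.73, SE 0.16, adjusted p = 0.0363) and Tmc6 (0.57, SE 0.11, adjusted p = 0.0133).

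The 1 lymphocyte marker tested, the immunoglobulin gene Ighm, did not pass (-1.20, SE 0.29, adjusted p = 0.0826). Its log2 values lay at 3.39 to 3.79 in BKO and 4.27 to 5.45 in FF libraries without overlap. With 1 tested member, adjustment over the list alone leaves the p-value as it is and adds nothing. Ucp1 could not be compared in cold, as its values were failed estimates. In total 51 genes passed, 3 higher and 48 lower, with Gstz1 and Klf15 among the lower ones; with the series as a covariate 17 passed and in the second series alone, where FF mice have 1 cold library, 8 passed, all of them lower. The covariate ended the calls of Elmod2, Tmc6, Pon1, Aldh4a1, Gcdh and Mccc2. The count was 33 without FF cold replicate 2 and 33 without BKO cold replicate 1. The Tmc6 call ended without FF replicate 2 or 4 or BKO replicate 1 or 3 (adjusted p = 0.0651, 0.0514, 0.0501 and 0.0731), and that of Elmod2 without FF replicate 1, 2, 3 or 4 or BKO replicate 1, 2 or 4 (adjusted p = 0.13, 0.0623, 0.181, 0.0674, 0.142, 0.17 and 0.171).

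In cold plus fasting Gstz1 and Hpd were lower as well, while Bcat2 did not pass (-0.58, adjusted p = 0.0647), and all libraries were of the second series. Gstz1 was at 30.9 ± 2.99 FPKM in BKO and 174 ± 10 FPKM in FF mice (SD, n = 3 each; log2 difference -2.46, SE 0.12, adjusted p = 1.26e-11). Adhfe1 fell by 1.74 (SE 0.11, adjusted p = 1.74e-09), Gstm7 fell by 1.69 (SE 0.14, adjusted p = 7.44e-08). Ttc7 fell by 1.17 (SE 0.16, adjusted p = 0.000438), Prodh fell by 1.11 (SE 0.17, adjusted p = 0.00149). Pon1 fell by 0.98 (SE 0.21, adjusted p = 0.044) and Pecr fell by 0.95 (SE 0.09, adjusted p = 5.37e-07). Of the 14 other amino acid catabolism genes 0 rose and 3 fell, Hpd (-1.45), Prodh and Aldh4a1 (-0.57; adjusted over the list alone, 0 and 8; adjusted p = 0.000601 with an estimated correlation). Of 21 branched-chain genes 0 rose and 2 fell, Aldh6a1 (-0.89) and Ivd (-0.59; adjusted over the list alone, 0 and 5; adjusted p = 0.294 with an estimated correlation). Elmod2 was higher, at 15 ± 1.69 against 7.43 ± 0.757 FPKM (log2 difference 0.92, SE 0.18, adjusted p = 0.0272), and Ucp1 was at 7920 ± 118 FPKM in BKO and 7750 ± 1010 FPKM in FF mice (log2 difference 0.04, SE 0.21, adjusted p = 0.992). In total 30 genes passed, 2 higher and 28 lower, and 728 had an unadjusted p under 0.05. The count was 16 without FF replicate 1, 17 without FF replicate 2, 19 without BKO replicate 2 and 19 without BKO replicate 3. The calls ended without FF replicate 1 or BKO replicate 3 for Aldh4a1 (adjusted p = 0.0598 and 0.0505), without FF replicate 1, 2 or 3 or BKO replicate 2 or 3 for Elmod2 (adjusted p = 0.137, 0.0691, 0.154, 0.215 and 0.074), and without FF replicate 1 or 2 or BKO replicate 1, 2 or 3 for Pon1 (adjusted p = 0.245, 0.281, 0.137, 0.107 and 0.0643).

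Across conditions, 11 genes were lower in BKO mice in each of the 4, namely Klf15, Gstz1, Adhfe1, Gstm7, Gstm2, Gstk1, Hpd, Pecr, Pxmp2, Aldh6a1 and Ivd. They include the tyrosine pathway genes Gstz1 and Hpd, 3 further glutathione transferases, Gstm7, Gstm2 and Gstk1, and the branched-chain pathway genes Aldh6a1 and Ivd. Fasted mice at room temperature and mice in cold shared 40 lower genes, against 2 for independent sets of these sizes, and mice in cold and in cold plus fasting shared 26, against 0.1. Fed and fasted mice at room temperature shared 18 lower genes, against 1, and fed mice and mice in cold shared 14, against 0.1. Fasted mice at room temperature and mice in cold plus fasting shared 24, against 1.2, and fed mice and mice in cold plus fasting shared 11, against 0.1. These comparisons use different libraries but share the estimate of spread of each gene from the common model. Their calls are therefore not independent, and more overlap than for independent sets arises from this alone. FF libraries were mostly of the first series in 3 of the 4 conditions, so that a shared effect of the series could add to these overlaps. Klf15, Gstz1, Adhfe1, Gstm7 and Pecr kept all 4 calls with each library left out and with the series as a covariate, which ended the fed calls of Gstk1, Gstm2, Hpd, Ivd, Pxmp2 and Aldh6a1 and the fasted call of Gstm2. In fed mice the calls ended without FF replicate 1 or 2 or BKO replicate 2 or 3 for Aldh6a1 (adjusted p = 0.186, 0.218, 0.125 and 0.211) and Pxmp2 (adjusted p = 0.113, 0.118, 0.158 and 0.0889), and without FF replicate 1 or BKO replicate 2 or 3 for Gstm2 (adjusted p = 0.186, 0.18 and 0.0519). They also ended for Hpd and Ivd as given above, and in cold plus fasting without FF replicate 2 for Gstk1 (adjusted p = 0.0596).

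**Figure D3:**
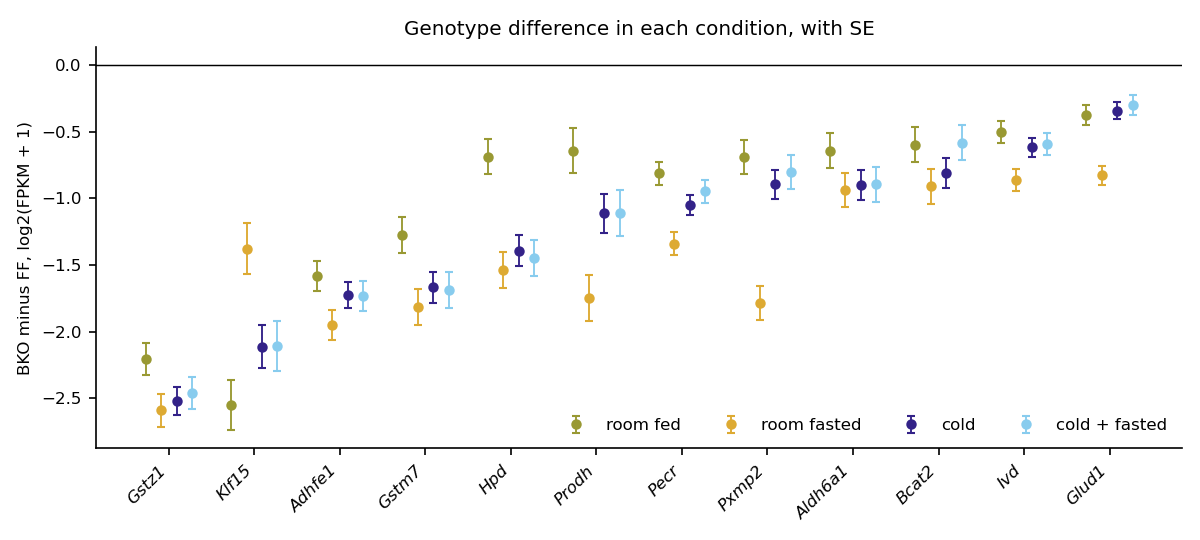
The difference between BKO and FF mice in log2(FPKM + 1) (y axis) is plotted for 12 genes (x axis) in each condition, with bars for the SE. Gstz1 lay between -2.59 and -2.21 and Adhfe1 between -1.95 and -1.58 in the 4 conditions, and Prodh lay between -1.75 and -0.64. By limma, Prodh (adjusted p = 0.217) and Bcat2 (adjusted p = 0.0576) did not pass in fed mice. Bcat2 (adjusted p = 0.0647) and Glud1 (adjusted p = 0.142) did not pass in cold plus fasting.

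The response to fasting at room temperature in FF mice included falls of Scd2 and Acly and rises of Hmox1 and Slc7a8. Scd2, a stearoyl-CoA desaturase (ENSMUSG00000025203.5, chromosome 19, 44293674 to 44306864), was at 6.24 ± 1.81 FPKM in fasted and 152 ± 63.5 FPKM in fed mice (SD, n = 3 each; log2 difference -4.35, SE 0.34, adjusted p = 4.21e-09). Acly was at 191 ± 76.1 against 1274 ± 479 FPKM (log2 difference -2.72, SE 0.30, adjusted p = 4.05e-07). The prostaglandin receptor Ptger3, the lactate receptor Hcar1, the fructose transporter Slc2a5 and the collagen chaperone Serpinh1 fell by 3.37, 3.32, 3.25 and 2.82. Hmox1, heme oxygenase 1 (ENSMUSG00000005413.7, chromosome 8, 75093621 to 75100589), was at 230 ± 149 FPKM in fasted and 4.53 ± 0.896 FPKM in fed mice (log2 difference 5.16, SE 0.44, adjusted p = 1.29e-08). The amino acid transporter Slc7a8 rose by 5.03, the ubiquitin ligase Trim63 by 4.41, the cytochrome P450 Cyp2b10 by 4.20, Fbxo31 by 3.31, the lipid transporter Mfsd2a by 3.01 and the argininosuccinate lyase Asl by 2.95. Of the genes fixed by name, the deiodinase Dio2 (2.10), Prodh (1.57), the coactivator Ppargc1a (1.38) and lipoprotein lipase Lpl (0.91) rose and Slc2a4 fell (-0.98), while Klf15 did not pass (-0.22, adjusted p = 0.39).

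In the same comparison 0 of 16 de novo lipogenesis genes rose and 15 fell (adjusted over the list alone, also 0 and 15; adjusted p = 0.384 with an estimated correlation), among them Acaca (-2.42) and Srebf1 (-2.37). In glycolysis and glucose uptake 1 of 19 rose and 14 fell (adjusted over the list alone, also 1 and 14; adjusted p = 0.384 with an estimated correlation), among them Pfkl (-1.74, SE 0.13) and Pkm (-1.03). In cholesterol synthesis 1 of 20 rose and 17 fell (adjusted over the list alone, also 1 and 17; adjusted p = 0.592 with an estimated correlation), among them Insig1 (-2.20) and Mvk (-1.18). In the glucocorticoid-responsive list 8 of 17 rose and 0 fell (adjusted over the list alone, 9 and 1; adjusted p = 0.646 with an estimated correlation), among them the metallothioneins Mt2 (2.81) and Mt1 (2.33) and Cdkn1a (1.95). In other amino acid catabolism 7 of 14 rose and 2 fell (adjusted over the list alone, also 7 and 2; adjusted p = 0.646 with an estimated correlation), among them Oat (0.96). In the interferon list 0 of 12 rose and 3 fell (adjusted over the list alone, 0 and 6; adjusted p = 0.851 with an estimated correlation). Among markers of other cells, 1 of 11 fibroblast markers rose and 4 fell (Col3a1, -1.90), 0 of 13 macrophage markers rose and 3 fell (H2-Ab1, -0.59), and 0 of 5 erythroid markers passed by limma, with a median of 0.65 (adjusted over the list alone, the same counts; adjusted p = 0.851 with an estimated correlation for each). The lymphocyte marker Ighm fell by 0.87 (SE 0.33, adjusted p = 0.0413), a call that ended without fed replicate 2 or 3 or fasted replicate 1, 2 or 3 (adjusted p = 0.0622, 0.181, 0.0876, 0.087 and 0.0699). In total 4763 genes changed, 2298 higher and 2465 lower in fasted mice. Every fasted FF library was of the first series, against 2 of the 3 fed ones, and a fit of only the libraries compared gave 3130 genes.

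The response to cold in FF mice included rises of Mb and Elovl3 and a fall of Car3. Mb, myoglobin (ENSMUSG00000018893.14, chromosome 15, 77015487 to 77050670), was at 53.6 ± 9.44 FPKM in cold (SD, n = 4) and 2.09 ± 0.685 FPKM in fed mice at room temperature (SD, n = 3; log2 difference 4.15, SE 0.30, adjusted p = 3.18e-09). The channel Hcn2 rose by 3.18, the mitochondrial carrier Slc25a34 by 2.95, the fatty acid elongase Elovl3 by 2.67, the secreted factor Bmp8b by 2.66 and the thioesterase Acot1 by 2.15 (SE 0.37). Car3, carbonic anhydrase 3 (ENSMUSG00000027559.5, chromosome 3, 14863512 to 14872523), was at 194 ± 32.8 against 2682 ± 414 FPKM (log2 difference -3.78, SE 0.21, adjusted p = 1.85e-11). The transcription factor Irf4, the signalling regulator Rgs2, Mycl and the lipoprotein gene Apoe fell by 2.64, 2.50, 2.22 and 2.20. Among genes fixed by name, Fgf21 (1.22) and Slc25a20 (0.56) also rose and Klf15 fell (-0.97, SE 0.18, adjusted p = 0.000416). Prodh rose as well, a call that ended without FF fed replicate 1 (adjusted p = 0.0731).

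In cold FF mice 6 of 23 thermogenic genes rose and 0 fell (adjusted over the list alone, 7 and 1; adjusted p = 0.429 with an estimated correlation), among them Acot11 (1.22) and Acsf2 (0.65). In glycolysis 13 of 19 rose and 0 fell (adjusted over the list alone, 14 and 0; adjusted p = 0.413 with an estimated correlation), among them Pfkl (0.94) and Tpi1 (0.64). In fatty acid oxidation 13 of 28 rose and 2 fell (adjusted over the list alone, also 13 and 2; adjusted p = 0.429 with an estimated correlation), among them Cpt2 (0.69) and Hadha (0.64). In cholesterol synthesis 11 of 20 rose and 1 fell (adjusted over the list alone, 13 and 1; adjusted p = 0.429 with an estimated correlation). In the glucocorticoid-responsive list 0 of 17 rose and 8 fell (adjusted over the list alone, 1 and 10; adjusted p = 0.429 with an estimated correlation), among them Tsc22d3 (-1.62). Markers of other cells moved as well. All 5 erythroid genes rose, with a median of 1.70, among them Hba-a2 (1.75) and Hbb-bs (1.70). Macrophage markers showed 7 falls and 0 rises among 13, among them Cd163 (-0.74) and H2-Aa (-0.51). Fibroblast markers showed 5 falls and 0 rises among 11, among them Col1a2 and Col3a1 (-1.07 each; adjusted over the list alone, 5 rose, 8 fell and 5 fell; adjusted p = 0.429 with an estimated correlation for each list). The 1 lymphocyte marker tested, Ighm, rose by 2.04 (SE 0.31, adjusted p = 5.86e-05). In total 2992 genes changed, 1686 higher and 1306 lower. The count was 1759 without FF fed replicate 1 and 1799 without FF fed replicate 2, and it was 117 in the second series alone, where 1 library of each group remained.

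Cold plus fasting in FF mice, compared with fed mice at room temperature, gave a response with many of the same leading genes as cold. Both responses were taken against the same fed libraries, which by itself makes them resemble each other. Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452), was at 7750 ± 1010 against 3273 ± 1050 FPKM (SD, n = 3 each, log2 difference 1.28, SE 0.21, adjusted p = 0.000404). Its fed libraries stood at 2647 and 2687 FPKM in the first series and 4486 in the second, to which all cold plus fasting libraries belong. Mb rose by 3.90, Hcn2 by 3.09, Bmp8b by 3.07, Slc25a34 by 2.77 and Elovl3 by 2.45, as did the cell cycle factor E2f2 by 2.08 and the ketone body gene Bdh1 by 2.07. Car3, Mycl, Net1, Svep1, Irf4 and Hcar2 fell by 3.42, 2.45, 2.43, 2.41, 2.41 and 2.35, and the ribosomal RNA gene n-R5-8s1 fell by 2.97. Fgf21 rose (1.12), and Klf15 fell by 0.63 (SE 0.19, adjusted p = 0.0216).

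In this response 13 of 19 glycolysis genes rose and 0 fell (adjusted over the list alone, 15 and 0), among them Pfkl (0.87). Similarly 13 of 28 fatty acid oxidation genes rose and 1 fell (adjusted over the list alone, 14 and 2), among them Hadha (0.68). Thermogenic genes rose in 7 cases of 24 and 1 fell (adjusted over the list alone, 8 and 1), among them Acsf2 (0.80). Cholesterol synthesis showed 6 rises and 0 falls among 20 genes (adjusted over the list alone, 9 and 0). In other amino acid catabolism 5 of 14 rose and 1 fell (adjusted over the list alone, 6 and 1), among them Got1 (1.69) and Fah (1.40). In the glucocorticoid-responsive list 0 of 17 rose and 7 fell (adjusted over the list alone, 0 and 9). All 5 erythroid markers rose, with a median of 1.69 (Hba-a1, 1.85), while 3 of 13 macrophage markers fell (H2-Aa, -0.63) and 4 of 11 fibroblast markers fell (Col3a1, -0.93), with 0 rising (adjusted over the list alone, 5 rose, 8 fell and 4 fell). For each of these lists the adjusted p = 0.434 with an estimated correlation. The lymphocyte marker Ighm, as log2 values, lay at 3.79 to 5.06 in cold plus fasting and 2.35 to 3.14 in fed FF libraries, without overlap. In total 2604 genes changed, 1469 higher and 1135 lower; with the series as a covariate 817 passed and in the second series alone, with 1 fed library, 295 did. The covariate ended the calls of Ucp1, Fgf21, H2-Aa and Klf15. The count was 1614 without FF cold plus fasting replicate 1, 1539 without FF fed replicate 1 and 1589 without FF fed replicate 2, and the Klf15 call ended without FF cold plus fasting replicate 2 or 3 or FF fed replicate 1 or 2 (adjusted p = 0.0687, 0.0923, 0.0858 and 0.0911).

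The response of BKO mice to fasting at room temperature again held falls of Scd2 and Acly and rises of Hmox1 and Slc7a8. Scd2 fell by 4.42 (SE 0.34, adjusted p = 4.46e-09), and Acly was at 61.9 ± 14.4 FPKM in fasted and 1061 ± 455 FPKM in fed mice (SD, n = 3 each; log2 difference -4.02, SE 0.30, adjusted p = 3.01e-09). Hcar1, the leptin gene Lep and the sorting receptor Sorcs2 fell by 3.28, 3.22 and 3.19. Hmox1 rose by 4.26 (SE 0.44, adjusted p = 2.46e-07), Slc7a8 by 3.99, Cyp2b10 by 3.21, the GDNF receptor Gfra1 by 3.12 (to 2 decimals, SE 0.36) and Fbxo31 by 2.82. Of the genes fixed by name, 6 rose, among them Klf15 (0.96, SE 0.19, adjusted p = 0.000603), Lpl (0.78), Cpt1b (0.49) and Slc25a20 (0.30), and Slc2a4 fell (-1.76). The other 2 were Pdk4 (0.61) and Prodh (0.46), whose calls ended without fed replicate 1, 2 or 3 or fasted replicate 2 for Pdk4 (adjusted p = 0.0606, 0.115, 0.0592 and 0.165) and without fed replicate 1, 2 or 3 or fasted replicate 1 or 3 for Prodh (adjusted p = 0.123, 0.121, 0.0536, 0.115 and 0.173).

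In fasted BKO mice 0 of 16 lipogenesis genes rose and 15 fell (adjusted over the list alone, 0 and 16; adjusted p = 0.108 with an estimated correlation), among them Pnpla3 (-2.96). Glycolysis showed 1 rise and 16 falls among 19 genes (adjusted over the list alone, also 1 and 16; adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis showed 1 rise and 16 falls among 20 genes (adjusted over the list alone, 1 and 17; adjusted p = 0.186 with an estimated correlation), among them Nsdhl (-2.06). In the PPAR and fasting-induced list 10 of 17 rose and 2 fell (adjusted over the list alone, 11 and 2; adjusted p = 0.134 with an estimated correlation), among them Vnn1 (1.58), Acot4 (1.57) and Cyp4a10 (1.28). In fatty acid oxidation 8 of 28 rose and 0 fell (adjusted over the list alone, 10 and 0; adjusted p = 0.623 with an estimated correlation), among them Ehhadh (2.13, SE 0.36) and Hsd17b10 (1.33). In the glucocorticoid-responsive list 8 of 17 rose and 1 fell (adjusted over the list alone, also 8 and 1; adjusted p = 0.588 with an estimated correlation), among them Mt1 (1.70) and Sult1a1 (1.64). In the interferon list 0 of 12 rose and 8 fell (adjusted over the list alone, 0 and 9; adjusted p = 0.266 with an estimated correlation), among them Bst2 (-1.10). Macrophage markers showed 0 rises and 6 falls among 13 (C1qa, -0.60) and fibroblast markers 1 rise and 4 falls among 11 (Col3a1, -1.44; adjusted over the list alone, 0 and 7, and 1 and 5; adjusted p = 0.674 and 0.671 with an estimated correlation). In total 3488 genes changed, 1636 higher and 1852 lower.

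The response of BKO mice to cold again included higher Mb and lower Car3. Mb was at 35.1 ± 6.75 FPKM in cold (SD, n = 4) and 2.86 ± 1.85 FPKM in fed mice (SD, n = 3; log2 difference 3.31, SE 0.30, adjusted p = 1.41e-07). Car3 was at 238 ± 104 against 3204 ± 298 FPKM (log2 difference -3.83, SE 0.21, adjusted p = 3.46e-11). Hcn2 rose by 3.04, Ttc25 by 2.66, Elovl3 by 2.56 and the amidoxime reductase Marc1 by 2.24. The secreted factor adipsin, Cfd, Pon1 and haptoglobin, Hp, fell by 2.26, 2.19 and 2.16. Fgf21 (1.13) and Slc25a20 (0.45) rose as well. Of 19 glycolysis genes 14 rose and 1 fell (adjusted over the list alone, 15 and 2; adjusted p = 0.223 with an estimated correlation), among them Gpi1 (1.09) and Pkm (0.87). Of 28 fatty acid oxidation genes 10 rose and 1 fell (adjusted over the list alone, 12 and 3; adjusted p = 0.363 with an estimated correlation), among them Hadha (0.58). Of 20 cholesterol synthesis genes 8 rose and 0 fell (adjusted over the list alone, 13 and 0; adjusted p = 0.352 with an estimated correlation), among them Cyp51 (0.95). Of 23 thermogenic genes 6 rose and 0 fell (adjusted over the list alone, also 6 and 0; adjusted p = 0.352 with an estimated correlation), among them Acsf2 (0.68). Of 13 macrophage markers 5 fell, of 11 fibroblast markers 5 fell (Col3a1, -0.94), of 11 endothelial markers 3 rose (Emcn, 0.77 and Pecam1, 0.52) and of 5 erythroid markers 4 rose, with a median of 1.12, and none moved the other way by limma (adjusted over the list alone, 10, 7, 3 and 5; adjusted p = 0.352, 0.352, 0.363 and 0.352 with an estimated correlation). In total 2060 genes changed, 1234 higher and 826 lower.

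The response of BKO mice to cold plus fasting included a rise of Ucp1, which was at 7920 ± 118 against 4384 ± 437 FPKM in fed mice (SD, n = 3 each; log2 difference 0.86, SE 0.21, adjusted p = 0.00867). Mb rose by 3.77, Hcn2 by 3.00, Elovl3 by 2.29, Bmp8b by 2.18 and Slc25a34 by 2.04, and Car3, Hcar1, Svep1 and Net1 fell by 3.92, 2.83, 2.47 and 2.42. Fgf21 (1.02) and Slc25a20 (0.48) rose, and Klf15 did not pass (-0.19, adjusted p = 0.525). Of 44 nuclear oxidative phosphorylation genes 17 rose and 0 fell (adjusted over the list alone, 20 and 0), among them Atp5b (0.53) and Ndufa9 (0.45). The median of this list was 0.20, and 0.11 with 7 rises without cold plus fasting replicate 3, which stood apart on the third component; 11 rose without cold plus fasting replicate 2, and 7 without fed replicate 1 or 2. Of 28 fatty acid oxidation genes 14 rose and 1 fell (adjusted over the list alone, 15 and 1), among them Acadvl (0.47). Of 19 glycolysis genes 13 rose and 1 fell (adjusted over the list alone, 14 and 1), among them Pkm (0.78). Macrophage markers showed 4 falls among 13 (H2-Ab1, -0.64), interferon genes 5 falls among 12 and erythroid markers 4 rises among 5, with a median of 1.19 (adjusted over the list alone, 5 fell, 5 fell and 5 rose). For each of these lists the adjusted p = 0.372 with an estimated correlation. In total 2409 genes changed, 1275 higher and 1134 lower; a fit of only the libraries compared gave 588. The count was 1425 without BKO cold plus fasting replicate 3, the library apart on the third component, and 1451 without BKO fed replicate 2.

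Genes such as Hmox1, Scd2, Mb and Car3 changed the same way in both genotypes. For fasting at room temperature 1143 genes were higher in both genotypes, against 295.9 for independent sets, 1426 were lower in both, against 359.3, and 11 went opposite ways. For cold 1003 were higher and 598 lower in both, against 163.8 and 84.9, and for cold plus fasting 905 and 588, against 147.4 and 101.3, with 0 opposite in each. The FF and BKO libraries are different ones, but the estimate of spread of each gene is shared, so the calls are not independent.

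**Figure D4:**
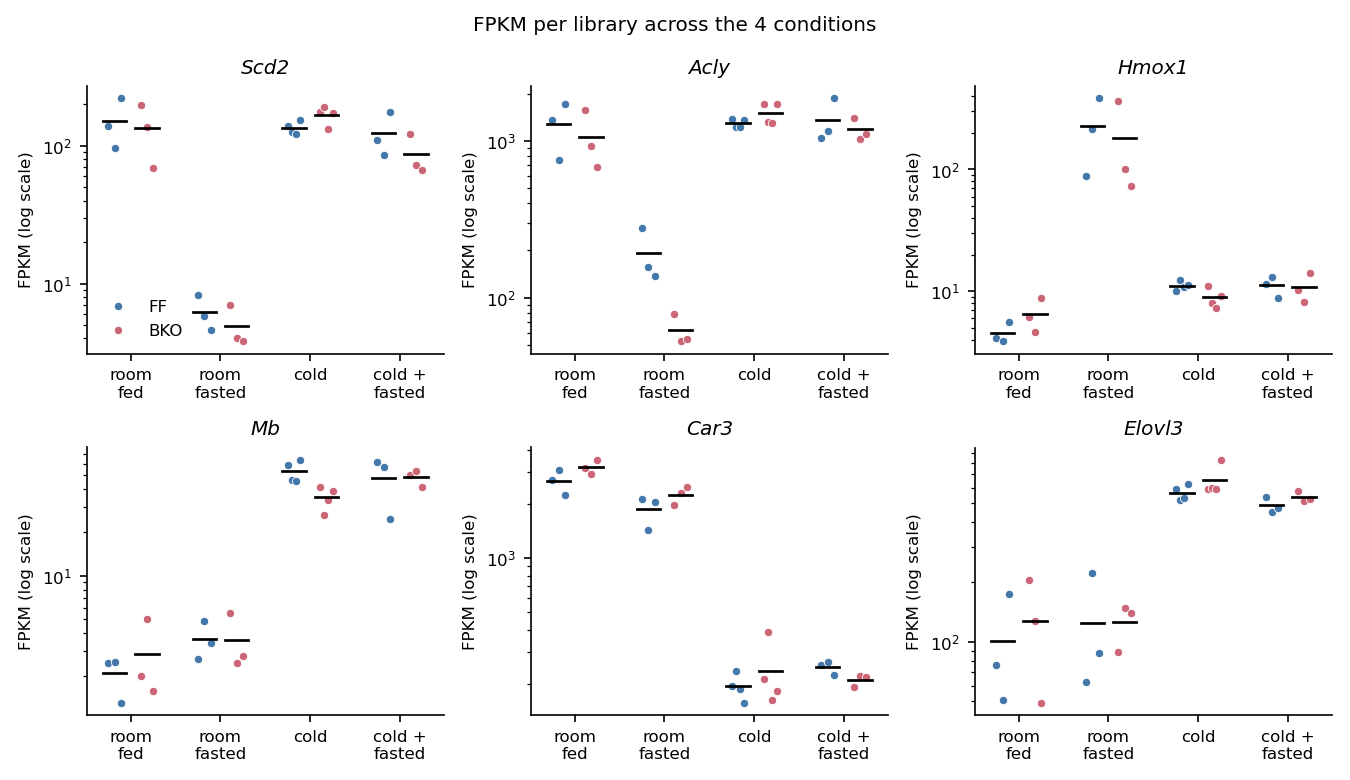
FPKM (y axis, log scale) of Scd2, Acly, Hmox1, Mb, Car3 and Elovl3 is plotted for each library by condition (x axis), with FF in blue, BKO in red and black lines for the group means. Mean Scd2 was at 6.24 FPKM in fasted and 152 FPKM in fed FF mice at room temperature, and mean Mb rose from 2.09 to 53.6 FPKM in cold FF mice.

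The response to fasting at room temperature was compared between genotypes as a difference of responses (n = 3 libraries in each of the 4 groups). Selenbp1 had a lower response in BKO mice, by -1.73 (SE 0.21, adjusted p = 0.000232), and Mfsd4b1 a higher one, by 1.25 (SE 0.21, adjusted p = 0.0046). Both calls held with each library left out in turn. Of 28 fatty acid oxidation genes 1 had a higher response in BKO mice and 0 a lower one (adjusted over the list alone, 14 and 0; adjusted p = 0.109 with an estimated correlation). Of 14 other amino acid catabolism genes 0 had a higher and 4 a lower response (adjusted over the list alone, 0 and 7; adjusted p = 0.0835 with an estimated correlation). Erythroid markers had a median of -0.99, and none of 5 passed by limma, also when adjusted over the list alone (adjusted p = 0.752 with an estimated correlation). In total 91 genes differed in response, 38 higher and 53 lower, and a fit of only the libraries compared gave 5. The count was 34 and 49 without FF fed replicate 1 and 2, 44 and 60 without BKO fed replicate 2 and 3, 241 and 33 without FF fasted replicate 2 and 3, and 41 and 25 without BKO fasted replicate 2 and 3.

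For cold and for cold plus fasting, 1 gene each differed in response between genotypes, the small RNA gene Gm22767, which was singled out after its values had been seen. It stood at 1.93 to 2.07 FPKM in the 3 FF libraries of fed mice and at 0 in the other 23. With a pseudocount of 0.1 both counts were 0, and without FF fed replicate 3 or BKO fed replicate 1 the counts were 3 or 4 for both responses. For cold plus fasting the count was also 2 without FF cold plus fasting replicate 3 or BKO cold plus fasting replicate 1. None of the fixed genes with values, such as Klf15 (0.44 in both), Elovl3 and Prodh, passed for either response by limma.

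Fasting in the cold was compared with cold alone within each genotype, a comparison added after the planned results had been seen. In FF mice (n = 3 against 4) 0 genes changed by limma, with 376 at an unadjusted p under 0.05. In BKO mice 1 gene changed, with 1110 at an unadjusted p under 0.05. That gene was Sh3bp5 (ENSMUSG00000021892.14, chromosome 14, 31359880 to 31436078), at 24.9 ± 2.2 FPKM in cold plus fasting (SD, n = 3) and 35.7 ± 0.895 FPKM in cold (SD, n = 4; log2 difference -0.51, SE 0.08, adjusted p = 0.0225). The call ended without BKO cold replicate 1, 2, 3 or 4 or BKO cold plus fasting replicate 3 (adjusted p = 0.105, 0.0602, 0.108, 0.12 and 0.154), while 4 genes passed without BKO cold plus fasting replicate 1, and in FF mice 1 passed without FF cold plus fasting replicate 2. The fasting response in the cold differed from that at room temperature for 2740 genes in FF mice, 1394 higher and 1346 lower, and for 1660 genes in BKO mice, 880 higher and 780 lower. In FF mice Scd2 differed by 4.17 (SE 0.46, adjusted p = 2.71e-06) and Hmox1 by -5.16 (SE 0.60, adjusted p = 4.79e-06). In BKO mice Acly by 3.66 (SE 0.41, adjusted p = 5.05e-06) and Slc7a8 by -4.02 (SE 0.37, adjusted p = 7.75e-07). In the lipogenesis list 12 of 16 genes differed upward in FF mice and 13 of 16 in BKO mice, with 0 downward (adjusted over the list alone, 13 and 13; adjusted p = 0.398 and 0.115 with an estimated correlation). With the series as a covariate the FF count was 1219.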

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

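Tests of explanations in this part were chosen after the results were seen, except the correlation with the library series; regroupings of the libraries had been planned, but how to read them was written down afterwards. Between genotypes, 1102 genes differed in fasted mice at room temperature, against 28, 51 and 30 in fed mice, in cold and in cold plus fasting, a contrast that depended on the setting: array weights gave 822 in fasted and 786 in fed mice, and fits of only the libraries compared gave 76 in fasted mice and 41 in cold. A series effect as the whole cause was examined by correlation across 12702 genes (genes are not independent replicates). The first minus second series in other FF groups correlated with FF minus BKO in fasted mice at r = 0.02. In cold plus fasting, where all libraries were of the second series, that r was -0.09. Each estimate of the series effect rests on a single FF library of the second series. The 2 estimates correlated with each other at only 0.12, so the low r cannot decide for or against a series effect. Larger differences in the same genes that differ in cold are a candidate explanation for a small part of the pattern at most. Over the genes called in fasted mice the slope of the cold difference was 0.14. Of the 575 higher genes there 0 were also called higher in cold, and of the 527 lower ones 40 were also called lower. Klf15, which was left out of the slopes, was at -1.38 in fasted mice and -2.11 in cold. Over 50 other genes called in cold, the slope on the cold difference was 1.08 in fasted mice and 0.86 in cold plus fasting. The difference of slopes was 0.22 (95% interval 0.07 to 0.42). This interval comes from resampling genes, so it measures the spread over genes and not over mice. A series effect could also give a steeper slope in fasted mice. FF libraries were all of the first series there and mostly so in cold, but not in cold plus fasting. Some other handling of the 3 FF libraries, all of the first series, cannot be told apart from genotype, because no BKO library of that series exists; with the series as a covariate 146 genes passed, while all 1102 kept their direction with a slope of 0.93, and the median SE was 1.46 times as large.

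Fasting changed 4763 genes in FF and 3488 in BKO mice at room temperature, but 0 and 1 genes in the cold, although array weights gave 496 genes for the latter (224 higher and 272 lower) and 0 for the former. Both cold groups might have been fasted like the fasted mice at room temperature. The slope of the cold response of FF mice on the fasting response of BKO mice was -0.07 over 3488 genes. It was 0.91 for the FF fasting response and 0.01 for cold plus fasting against cold. A slope near that of the FF fasting response would be forecast only if cold itself left those genes unchanged. Glycolysis and cholesterol synthesis genes moved opposite ways with fasting and in cold in FF mice, so the slope cannot decide this. Too few libraries to see a response at least 0.5 times as large is argued against in FF mice. There the intervals of 389 of 449 genes, or 86.6%, lay below 0.5 times the change that fasting caused in BKO mice at room temperature. The genes were picked for that change, which can overstate it, and smaller responses are not excluded. For BKO mice too few libraries was not tested, and 1110 genes had an unadjusted p under 0.05 by limma there. A weaker fasting response in the cold, or a shorter fast, may explain the pattern, and these were not tested, as the labels give no duration. Fasting of both cold groups is not excluded either.

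Elmod2 (chromosome 8, 83312632 to 83332486) and Tbc1d9 (83165352 to 83272934), the tested genes on either side of Ucp1 (83290352 to 83298452), were higher in BKO mice by 0.74 and 0.48 on average (for Tbc1d9, adjusted p = 0.188 with the series as a covariate), while the next genes outward, Rnf150 (-0.08) and Scoc (-0.01), were not. Reads running on from Ucp1 are argued against in FF mice, in which Ucp1 rose by 1.28 in cold plus fasting (no longer called with the series as a covariate) and Elmod2 fell by 0.55 (SE 0.18, adjusted p = 0.0383), while Tbc1d9 was at 0.11 (SE 0.14, adjusted p = 0.618). The library series is argued against by Elmod2 in cold plus fasting, where all libraries were of the second series, at 0.92 (SE 0.18, adjusted p = 0.0272; fitted alone, the second series gave 0.92 with adjusted p = 0.0662; leaving out FF replicate 1, 2 or 3 or BKO replicate 2 or 3 gave adjusted p = 0.137, 0.0691, 0.154, 0.215 and 0.074). Of 10649 other genes with tested neighbours on both sides, 0 had both neighbours at least 0.48 higher, but that bound is the difference of Tbc1d9 itself, so the count restates the pattern and does not bear on its cause, and copies of the region carried by the Cre transgene were not tested. Tbc1d9 did not pass in cold plus fasting (0.61, SE 0.14, adjusted p = 0.0867; second series alone, adjusted p = 0.0805), and the construct of the transgene is not in the labels.

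Outlying libraries were looked for in 214 groups of 4 values, of which 15 had a library far from the rest, and chance gives about 1 in 20 groups. In FF cold these were Acadvl (1500 FPKM), Irf4 (6.39) and Peg3 (14) in replicate 2, Arntl (5.72) and Hbb-bs (216) in replicate 3, E2f2 (15.5) and Tsc22d3 (9.27) in replicate 4 and Tmc6 (4.41) in replicate 1. In BKO cold they were Dbp (7.39), Net1 (29.8) and Prodh (6.85) in replicate 3, Elovl3 (830) and Ndufa9 (478) in replicate 4, Hcn2 (10.6) in replicate 2 and Pxmp2 (8.42) in replicate 1.

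Responses that differed between groups by a test of the difference itself were the following. The response to fasting at room temperature differed between genotypes for 91 genes, and of those named the difference, BKO minus FF, was 1.96 for Lgr6, 1.25 for Mfsd4b1, 1.17 for Klf15, 1.13 for Spata22, 1.06 for Plin1, 0.96 for Cideb, 0.59 for Cpt2, -0.78 for Slc2a4, -0.85 for Hpd, -1.11 for Prodh, -1.41 for Slc25a33, -1.73 for Selenbp1, -2.51 for Dio2 and -2.56 for Plk3. Without FF fed replicate 1 each of these but Mfsd4b1 and Selenbp1 lost its call (adjusted p = 0.0544 to 0.136). Some of these calls were also lost without each other library of the 4 groups, with adjusted p of at most 0.137. The cold and cold plus fasting responses differed between genotypes for 1 gene each. The fasting response in the cold minus that at room temperature passed for 2740 genes in FF mice, with 4.17 for Scd2, 3.15 for Slc2a5, 3.15 for Ptger3, 2.76 for Serpinh1, 2.74 for Acly, 1.01 for Slc2a4, -0.90 for Lpl, -1.32 for Prodh, -1.83 for Ppargc1a, -2.38 for Dio2, -3.53 for Cyp2b10, -4.42 for Trim63, -4.75 for Slc7a8, -5.16 for Hmox1 and -5.60 for Nr4a1. In BKO mice it passed for 1660 genes, with 3.93 for n-R5-8s1, 3.66 for Acly, 3.44 for Scd2, 2.80 for Pnpla3, 2.74 for Ppp1r3b, 1.58 for Slc2a4, -0.80 for Lpl, -2.63 for Pik3ip1, -2.83 for Peg3, -3.17 for Gfra1, -4.02 for Hmox1 and -4.02 for Slc7a8.

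Regrouping the libraries, over 12702 genes, gave a share under 0.05 for the average genotype difference (377 genes, at most 11 in 99 other splits drawn, so 1 of 100). The share was also under 0.05 for genotype in cold (51 genes, at most 3), cold in FF mice (2993, at most 1224) and cold in BKO mice (2061, at most 922), each 1 of 35 splits. These shares are the smallest possible and were not adjusted over the comparisons, so they make chance less likely without excluding it. For genotype in cold the real split also nearly follows the series, as most FF libraries and no BKO library were of the first series. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05: the real count and the highest other were 28 and 38 for genotype in fed mice, 1103 and 300 in fasted mice, 30 and 3 in cold plus fasting, 4761 and 53 for fasting in FF mice, 2600 and 19 for cold plus fasting in FF mice, 3485 and 1 for fasting in BKO mice, and 2408 and 3 for cold plus fasting in BKO mice. The split with 38 genes exchanged the replicates 3 of fed mice, which leaves both first-series libraries together in the same group as before, so that it exceeds the real count without changing the make-up by series. Chance was not excluded for differences of responses between genotypes, where 12, 31 and 38 of 100 splits gave as many genes as the 91, 1 and 1 found for fasting, cold and cold plus fasting, with up to 854, 39 and 35; splits far above the real count point to the structure of the samples, as exchanging genotypes within a single condition adds the genotype differences of both. For cold plus fasting against cold in FF mice the real count was 0, which all 35 of 35 splits reach whatever the data (at most 1), so that regrouping says nothing there. Chance was not excluded either for the same comparison in BKO mice, with 1 gene (2 of 35, at most 1), nor for the fasting response in the cold minus that at room temperature, with 2740 genes in FF mice (5 of 100 splits, up to 2910) and 1660 in BKO mice (12 of 100, up to 2522), where exchanging labels within 1 temperature likewise keeps the large response at the other.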

How the results depend on the processing

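Of 381 results for named genes, all of which passed, 381 kept their direction and 230 their call in each alternative in which they were run; not every result was run in each. These results were chosen for passing, and the alternatives use the same libraries or a part of them. The kept direction is therefore no independent support. The comparisons of cold plus fasting with cold and the corresponding differences of fasting responses were added after the planned results had been seen. No paired analysis was possible because the labels pair no libraries and replicate numbers only follow the order of submission. That order was not without structure: deviations from the group means correlated at 0.06 on average between libraries with the same number in different groups and at -0.03 otherwise (2 of 2000 random orders were as high, a test added after the results were seen), and replicate 3 had the fewest genes at 1 FPKM in 8 of 8 groups. The cause is unknown, and the counts and regroupings take no account of it. Depth is unknown, so what it limits could not be assessed. For the changes below the cause was not tested, except that fits of fewer libraries have fewer samples and the stricter filter tests fewer genes.

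Array weights gave 1344 genes for the average genotype difference (377), 786 for genotype in fed mice (28), 108 in cold (51), 140 in cold plus fasting (30), 6681 and 5713 for cold and cold plus fasting in FF mice (2992 and 2604), 3286 and 3906 in BKO mice (2060 and 2409), 315, 115 and 101 for the differences between genotypes in the responses to fasting, cold and cold plus fasting (91, 1 and 1), 496 for cold plus fasting against cold in BKO mice (1) and 2602 for its difference of fasting responses (1660). The library series as a covariate gave 59 for the average, 7 in fed mice, 146 in fasted mice (1102), 17 in cold, 817 for cold plus fasting in FF mice, 2 for the difference of cold responses and 1219 for the difference of fasting responses in FF mice (2740). Only the libraries compared gave 6 in fed mice, 76 in fasted mice, 6 in cold plus fasting, 3130 for fasting in FF mice (4763), 588 for cold plus fasting in BKO mice, 5 and 2 for the differences of fasting and cold plus fasting responses between genotypes, and 2 and 0 for cold plus fasting against cold in FF and BKO mice (0 and 1). Libraries numbered 15 or above gave 9 in fed mice, 8 in cold, 117 and 295 for cold and cold plus fasting in FF mice, and 0 for cold plus fasting against cold in BKO mice. A mean of at least 5 FPKM gave 18 in fed mice, 1604 for cold plus fasting in BKO mice, and 0 and 0 for the differences of cold and cold plus fasting responses; a pseudocount of 0.1 gave 0 and 0 there and 1 for cold plus fasting against cold in FF mice; quantile normalization gave 2 and 2; and no filter gave 2 and 2 for cold plus fasting against cold in FF and BKO mice.

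Leaving out 1 library at a time gave ranges of 235 to 624 for the average, 13 to 105 in fed mice, 421 to 1390 in fasted mice, 33 to 45 in cold, 16 to 41 in cold plus fasting, 3788 to 4384, 1759 to 3237 and 1539 to 2830 for fasting, cold and cold plus fasting in FF mice, 2599 to 3193, 1390 to 1953 and 1425 to 2384 in BKO mice, 25 to 241, 1 to 4 and 1 to 4 for the differences between genotypes, and 0 to 1 and 0 to 4 for cold plus fasting against cold in FF and BKO mice. The libraries that moved a count by over 1.5 times are named with each count.

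With the estimated correlation the gene lists past the threshold went from 8 to 2 for the average, 7 to 1 in fed mice, 10 to 1 in fasted mice, 6 to 4 in cold, 4 to 1 in cold plus fasting, and from 8, 12, 14, 11, 16, 9, 7, 9 and 4 to 0 in the responses and their differences. With the series as a covariate 12 passed in fed mice and 12 in cold.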

Other observations

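In both genotypes and each challenge the clock output gene Dbp was lower and the clock activator Arntl higher than in fed mice at room temperature. Dbp differed by -2.39 to 2 decimals with fasting, -1.99 in cold and -1.89 in cold plus fasting in FF mice, and by -1.95, -1.11 and -1.35 in BKO mice, and Arntl by 1.21, 1.10 and 1.20 in FF mice and by 0.86, 0.86 and 0.96 in BKO mice. Of 18 circadian clock genes, 5 rose and 5 fell with fasting in FF mice, 2 and 4 in cold, and 4 and 5 in cold plus fasting, and in BKO mice 4 and 3, 3 and 1, and 3 and 4. The Dbp call in cold BKO mice ended without BKO fed replicate 3 (adjusted p = 0.0519). Times of tissue collection are not in the labels.

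Of 9 creatine and calcium cycling genes, 2 rose and 3 fell with fasting, 3 and 2 in cold and 3 and 2 in cold plus fasting in FF mice, and 2 and 3, 2 and 1, and 2 and 1 in BKO mice. Creatine kinase B, Ckb, rose by 1.83 with fasting, 1.82 in cold and 2.00 in cold plus fasting in FF mice and by 1.23, 1.31 and 1.49 in BKO mice. The phosphatase gene Alpl rose in cold by 1.51 in FF and 1.24 in BKO mice, and the creatine transporter Slc6a8 rose with fasting by 1.56 in FF and 1.60 in BKO mice and fell by 0.69 in cold FF mice. Of 14 integrated stress response genes, 6 rose and 3 fell with fasting in FF mice and 5 and 4 in BKO mice, and 3 and 3 in cold in FF mice and 2 and 2 in BKO mice (adjusted over the list alone, 6 and 3, 5 and 4, 3 and 4, and 2 and 4; adjusted p = 0.851, 0.674, 0.871 and 0.833 with an estimated correlation). Pck2 (2.19 and 1.77) and Trib3 (1.14 and 1.88) rose with fasting in FF and BKO mice while Atf5 fell (-1.37 and -0.98), and Atf5 rose in cold (0.76 and 1.11). In fasted mice at room temperature, BKO mice had higher Phgdh (1.03), the first enzyme of serine synthesis, and lower Chac1 (-1.25), Trim63 (-1.85) and Foxo1 (-1.16) than FF mice. All FF libraries of that condition were of the first series and all BKO ones of the second, so series and genotype cannot be separated there. Foxo1 was also lower in cold than in fed FF mice (-1.06). Between BKO and FF mice fasted at room temperature 2 of 14 integrated stress response genes were higher and 2 lower, and 2 of 14 FoxO and insulin-repressed targets were higher and 5 lower (adjusted over the list alone, 2 and 3, and 2 and 5; adjusted p = 0.917 and 0.744 with an estimated correlation).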
